A study of Mus musculus with 9 samples.

How the data were processed

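RNA was measured by sequencing in GFP-positive cells sorted from dissociated mouse limbs of E12.5 embryos. Per the labels, the series has 9 samples: 3 controls carrying Cre at 1 Shox2 allele, 4 mutants that also carry a mutant second allele, and 2 whole limbs. The sample titles and descriptions give a litter number from 1 to 3, and litter 1 has 2 mutant samples. The deposited expression table used here has 6 value columns, 1 per genotype and litter. Whole limbs were not analysed here. Whether the litter 1 mutant column is 1 of the 2 samples or both combined is not given in the sources used here.

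Per the submitters' processing notes, reads were handled with TopHat and Cuffdiff on the mm9 build. Versions, annotation and filters are not given in the sources used here. Per the file headers, the values were normalised by Cuffdiff with its geometric method. The word FPKM is absent from the header. The deposited values were taken as FPKM because Cuffdiff reports that unit and the values are decimals from 0. The header states the normalisation above each litter separately, so levels set across litters may rest on separate scalings. No coordinates are given because the annotation used here is of another build.

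The table had 24102 rows with 23809 distinct names. A shared name occurred in 480 rows, several gene names in 352, a name altered to a date in 26, and a value of 0 in all columns in 5246. Gapdh, a glycolytic enzyme with many near-identical pseudogenes, was listed at between 0.656 and 6.54 FPKM, so genes with such copies are uncertain here. A value of 0 in 1 column against 5 or more in every other column was found in 7 rows of control 2 and 1 row of mutant 2.

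The sum of FPKM per column ran from 347708 to 439109, which is no measure of depth, and depth is unknown. Low values were compared within litters. In litter 3, 44.5% of 1332 rows under 0.15 FPKM in both columns had a log2 ratio within 0.05 of -1, 0 or 1. The share within 0.05 of 0 alone was 23.9%. A read may thus have been worth about as much in both columns, but a 2-fold difference would also give such ratios. The shares within 0.05 of -1, 0 or 1 were 8.13% in litter 1 and 6.12% in litter 2, where no relative depth was derived.

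The deposited gene list holds symbols without values, and its file name calls its members directly repressed by Shox2. How the list was made is not given in the sources used here. Of its 1352 distinct symbols, 1271 matched a row exactly, 33 matched through a synonym in a RefSeq gene table of GRCm38.p6, and 48 matched no row. Of 455 symbols in the 21 fixed lists, 447 matched.

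Mutants were compared with controls by limma 3.58.1 in R 4.3.3, with an intensity trend, on log2(FPKM + 1). A row entered the test at 1 FPKM or more in at least 3 of the 6 columns, which left 12314 rows. Fold changes on this scale understate the change of low genes. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Gene lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the 20 lists with at least 5 tested members. Camera was repeated with an estimated correlation. An exact permutation test of 3 columns against 3 cannot give a two-sided p below 0.1.

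The design, the gene lists, the alternatives and the rule for named genes were fixed before the data were examined. That plan was for 3 control and 4 mutant samples, and the comparison and row filter had to be adapted to the 6 columns of the table. A planned comparison of controls with whole limbs was not run. The rule took Shox2, then up to 10 genes per direction past the threshold with the largest change, a mean of 2 FPKM or more and no overlap between groups. With fewer past the threshold, it took the smallest unadjusted p up to 5 per direction, within the same limits. It also took up to 3 members of each fixed list with the smallest p and 5 of the deposited list with the largest change. Rows naming several genes and date-like names were left out of the 5 per direction, a step added after the data were seen. Runx2, Mmp9, Hspa1a, Hspa1b, Slc2a1, Bnip3, Slc16a3, Hk2, Pdk1, Gapdh, Gap43, Tubb3, Nefm, Snora16a, Hoxc9, Hoxc10 and Hoxc11 were chosen after their values were seen.

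The litter numbers pair the columns, since the descriptions say that a number marks a litter. Deviations from the group means correlated between the mutant and control columns of a litter at 0.87, 0.57 and 0.77 across genes in litters 1, 2 and 3, above each such correlation across litters. In log2 values the columns of litter 2 correlated at 0.952, below the highest value between litters, 0.968. The first principal component held 61.5% of the variance and set litter 1 apart. The fixed design had no litter term, and a fit with litter as a block was chosen beforehand as a second fit. Nothing in the labels says how many embryos made up a column.

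The fit was tested on simulated data made from the real rows, with 100 rows changed by 2-fold and 100 by 4-fold. Without the block it recovered 12% and 81% of these over 12314 rows, with 2 false calls. With the block it recovered 54% and 88%, with 4 false calls. Camera called 100% of 50 simulated lists of 25 members shifted by 0.5 on the log2 scale and 0% of unshifted ones. The noise of simulated rows was drawn independently, so lists of correlated genes were not tested. Estimated correlations in the real lists were 0.12 for the BMP pathway, 0.14 for synapses and axon guidance and 0.29 for limb patterning. They were 0.35 for hypertrophy and osteoblasts and 0.06 for muscle connective tissue, so the 0% is no error rate for these lists. Alternatives covered the pseudocount, the filter on low values, rescaling, quantile normalisation, the trend, column weights, the litter block, leaving out each column, and the estimated correlation. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.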

Results

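The cells came from mouse limbs at E12.5. Shox2 encodes a homeodomain transcription factor of the proximal limb. Cre recombinase made from the Shox2 locus switches the mTmG reporter from a red to a green membrane protein, and green cells were sorted. Control cells had 1 Cre allele and a normal allele of Shox2, and mutant cells had the Cre allele and a mutant allele. Values in FPKM were available here for 3 control and 3 mutant columns from 3 litters, and all errors below are over n = 3 columns per group. The comparison asks which transcripts differ in Shox2-lineage cells when the gene is disrupted.

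Shox2 itself was at 216 ± 6.31 FPKM (SD, n = 3) in the controls and 44.0 ± 45.9 FPKM (SD, n = 3) in the mutants. In litter 1 it was at 217 FPKM in the control and 16.7 FPKM in the mutant, and in litter 2 at 222 and 18.3 FPKM. In litter 3 it was at 210 FPKM in the control and 96.9 FPKM in the mutant, or 46.2% of its control, against 7.68% and 8.25% in litters 1 and 2. The log2 change was -2.75 (SE 0.64), lower in 3 of 3 litters. It did not pass limma's threshold over all genes (adjusted p = 0.803, or 0.0998 with litter as a block). Without mutant replicate 3 it was -3.56 and passed (limma adjusted p = 0.0115), where the adjusted p over all alternatives ran from 3.68e-05 to 1.00. The exact two-sided permutation p was 0.1, the smallest that 3 columns against 3 can give. The labels do not say which part of Shox2 the alleles remove, so reads left in the mutants cannot be assigned to a transcript.

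**Figure D1:**
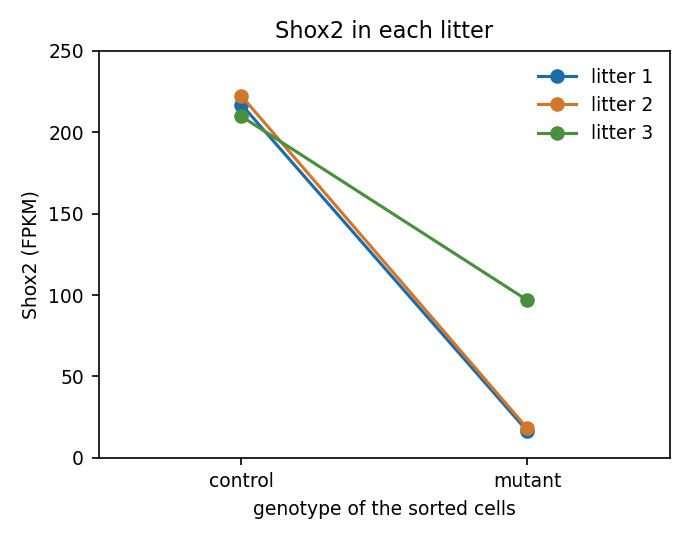
Shox2 in FPKM (vertical axis, from 0) in the control and mutant column of each litter, with a line joining the columns of a litter. The mutant columns of litters 1 and 2 sit at 16.7 and 18.3 FPKM and that of litter 3 at 96.9 FPKM.

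Among genes with a mean of 2 FPKM or more and no overlap between groups, those with the smallest unadjusted p higher in the mutants were Cbln2, Mdga2, Gdf5, Cdh10 and Sall1, each higher in 3 of 3 litters. Cbln2, a secreted organiser of synapses, was at 10.2 ± 1.60 FPKM in the controls and 34.5 ± 2.69 FPKM in the mutants, a log2 difference of 1.67 (SE 0.16). Gdf5, a BMP-family ligand of forming joints, was at 21.3 ± 2.68 and 46.7 ± 2.47 FPKM, and the cadherin gene Cdh10 at 4.95 ± 0.872 and 12.7 ± 1.40 FPKM. Mdga2, which encodes a neuroligin-binding adhesion protein, was at 0.829 ± 0.0513 and 3.41 ± 0.499 FPKM, and Sall1, a zinc-finger transcription factor, at 2.42 ± 0.209 and 7.20 ± 1.63 FPKM. Among those lower in the mutants within the same limits, the homeobox gene Meox1 was at 33.4 ± 1.75 FPKM in the controls and 13.0 ± 2.49 FPKM in the mutants, a log2 difference of -1.32 (SE 0.17). Nostrin, a trafficking factor of nitric oxide synthase, was at 4.03 ± 0.563 and 1.34 ± 0.417 FPKM, and Hes1, a repressor downstream of Notch, at 34.5 ± 5.72 and 18.8 ± 1.23 FPKM. The protease gene Klk8 was at 4.79 ± 0.353 and 2.54 ± 0.423 FPKM, and Nt5e, which encodes the ectonucleotidase CD73, at 7.34 ± 1.74 and 3.54 ± 0.0882 FPKM. These 10 genes did not pass the adjusted threshold, with the lowest adjusted p, 0.247 in limma, for Cbln2. With litter as a block they did not pass either, but lay closer. The limma adjusted p was then 0.0643 for Cbln2, Mdga2, Gdf5, Cdh10, Sall1 and Meox1. It was 0.0663 for Nostrin, 0.0817 for Hes1, 0.126 for Klk8 and 0.103 for Nt5e.

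**Figure D2:**
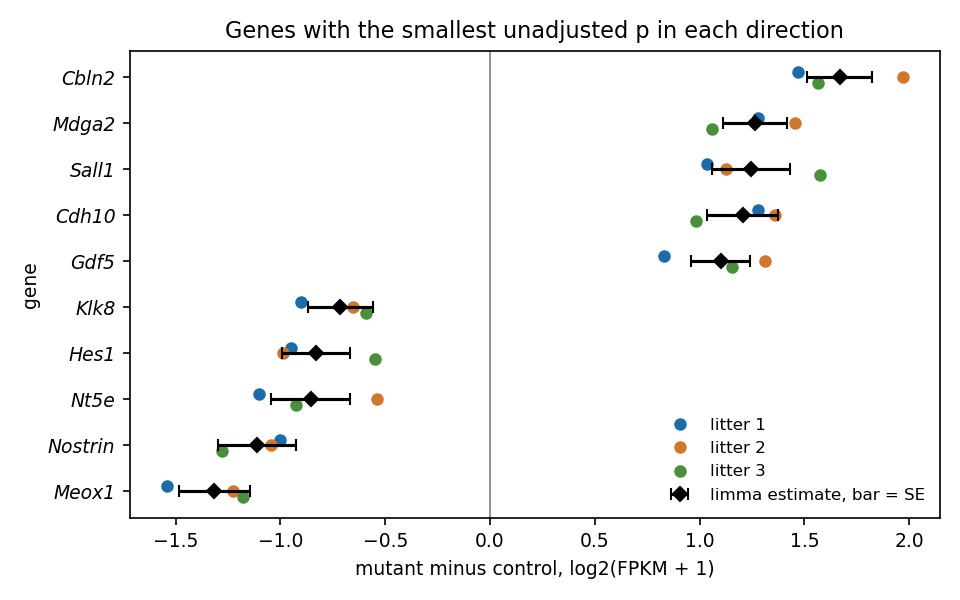
Difference of the mutant from the control column on the log2(FPKM + 1) scale (horizontal axis) for 10 genes, with coloured points for litters and black diamonds with bars for the limma estimate and its SE. Cbln2 lies at 1.47, 1.97 and 1.56 in litters 1, 2 and 3, and Meox1 at -1.54, -1.23 and -1.18.

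Over 12314 rows, limma called 0 genes higher and 0 lower. At an unadjusted p under 0.05 there were 272 higher and 167 lower, 439 in all. With litter as a block limma again called 0 genes, with 658 higher and 775 lower at an unadjusted p under 0.05, 1433 in all, and a lowest adjusted p of 0.0643 shared by 19 genes. Column weights in limma called 15 genes, 12 higher and 3 lower, among them Cbln2, Gdf5, Cdh10, Mdga2, Sall1, Gria2, Meox1, Nostrin and Panx3. Leaving out control replicate 3 gave 1 call, the small nucleolar RNA Snora16a, and leaving out mutant replicate 3 gave 1 call, Shox2. The blocked fit called 303 genes without the litter 2 pair, 27 without the litter 3 pair and 0 without the litter 1 pair. Groups did not overlap in 520 rows higher and 619 lower in the mutants, 9.25% of rows, against 10% by chance for columns that could be exchanged. Columns of a litter are alike, and the 3 other splits that part each litter left 2.84%, 3.34% and 2.67% of rows without overlap. The direction was shared by 3 litters in 38.0% of rows, against 25% by chance and 20.2% to 21.0% in those 3 splits.

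Genes of the BMP pathway, a fixed list of ligands, receptors, antagonists and targets, rose as a group in the mutants, with a median log2 change of 0.28 over 26 tested members (camera adjusted p = 4.76e-08). The call was lost with the stricter correlation (adjusted p = 0.355 with an estimated correlation). No member passed over all genes, and 1, Gdf5, passed when adjusted over the list alone, or 5 with the litter block. Bmp3, a ligand that opposes BMP signalling, was at 3.76 ± 1.06 FPKM in the controls and 6.17 ± 0.484 FPKM in the mutants. Id2, an inhibitor of helix-loop-helix factors, was at 106 ± 13.5 and 153 ± 23.1 FPKM. Members were higher in all 3 litters for 14 genes and lower in all 3 for 3 genes. At the preset correlation 5 lists passed camera, given here and in the next paragraphs. The 3 other splits that part each litter gave 2, 7 and 9 passing lists, so such calls also arose with wrong labels.

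Genes of synapses and axon guidance rose as a group, with a median log2 change of 0.32 over 25 tested members (camera adjusted p = 5.10e-08). This call too was lost with the stricter correlation (adjusted p = 0.355 with an estimated correlation). Gria2, a glutamate receptor subunit, was at 1.94 ± 0.420 FPKM in the controls and 9.70 ± 3.91 FPKM in the mutants. Sema3d and Sema3c, secreted guidance cues also made by mesenchyme, were at 4.43 ± 1.32 and 9.47 ± 0.656 FPKM, and at 16.8 ± 0.829 and 25.9 ± 4.09 FPKM. Adjusted over the list alone, 2 members passed, or 11 with the litter block, 9 higher and 2 lower. The list's median was 0.19 without control replicate 2, and 0.50 and 0.18 with the block without the litter 1 and litter 2 pairs. Markers of nerve and glia had medians of 0.43, -0.12 and 0.22 in litters 1, 2 and 3, where this list had 0.20, 0.47 and 0.25.

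Limb patterning transcription factors rose as a group, with a median log2 change of 0.13 over 31 tested members (camera adjusted p = 0.00322, and adjusted p = 0.793 with an estimated correlation). Lhx9, a LIM homeobox factor, was at 8.88 ± 1.11 FPKM in the controls and 14.5 ± 0.163 FPKM in the mutants, and Pax9, a paired-box factor, at 1.10 ± 0.274 and 2.54 ± 0.326 FPKM. Adjusted over the list alone, 4 members passed, namely Sall1, Lhx9 and Pax9 higher and Shox2 lower, or 6 with the litter block, 4 higher and 2 lower. The list's call was lost without control replicate 1 (median 0.03, camera adjusted p = 0.135), mutant replicate 2 (0.08, adjusted p = 0.125) or mutant replicate 3 (0.03, adjusted p = 0.0577), and its median was 0.34 without mutant replicate 1. The call was also lost among rows with a mean of 5 FPKM or more (0.06, adjusted p = 0.0546) and without the litter 3 pair (0.08, adjusted p = 0.148, or 0.136 with the block), while the median was 0.21 with quantile normalisation, 0.23 with column weights and 0.22 with the block without the litter 1 pair. Without the members that are in the deposited list, which may have been chosen on these samples, the 16 others had a median of 0.04 and missed the threshold (camera adjusted p = 0.196, or 0.0880 before adjustment).

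Genes of hypertrophic chondrocytes and osteoblasts fell as a group in the mutants, with a median log2 change of -0.35 over 19 tested members (camera adjusted p = 0.000418, and adjusted p = 0.729 with an estimated correlation). Panx3, a channel of osteoblasts and hypertrophic chondrocytes, was at 2.28 ± 0.786 FPKM in the controls and 0.195 ± 0.122 FPKM in the mutants. Sp7, the osteoblast transcription factor osterix, was at 4.78 ± 1.37 and 1.54 ± 0.612 FPKM, and Alpl, which encodes alkaline phosphatase, at 4.80 ± 2.74 and 1.14 ± 0.0935 FPKM. These 3 passed when adjusted over the list alone, and 7 members, all lower, passed with the litter block, among them Runx2, a master regulator of osteoblasts, at 16.2 ± 6.12 and 8.37 ± 4.13 FPKM. The list's call was lost among rows with a mean of 5 FPKM or more (adjusted p = 0.231). Its median was -0.58 without control replicate 1, -0.16 without control replicate 2 or mutant replicate 1, and -0.53 without mutant replicate 2. It was -0.21 without a filter on low values, -0.19 with a mean of 5 FPKM or more and -0.15 with column weights.

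Muscle connective tissue genes fell as a group, with a median log2 change of -0.24 over 11 tested members (camera adjusted p = 0.0464, and adjusted p = 0.637 with an estimated correlation). With the litter block the list missed the threshold (adjusted p = 0.0963). It also missed without control replicate 1 (0.135), control replicate 3 (0.176, median -0.15), mutant replicate 1 (0.0870) or mutant replicate 2 (0.125), and the median was -0.36 without mutant replicate 3. The call was lost as well with quantile normalisation (adjusted p = 0.0537), with a mean of 5 FPKM or more (0.0546), without the litter 3 pair (0.0809), and with the block without the litter 1, 2 and 3 pairs (0.0828, 0.0927 and 0.122). Postn, which encodes the matrix protein periostin, was at 75.8 ± 12.3 FPKM in the controls and 52.1 ± 3.08 FPKM in the mutants. Aldh1a2, an enzyme of retinoic acid synthesis, was at 52.3 ± 6.06 and 37.7 ± 9.88 FPKM. Adjusted over the list alone, 0 members passed, or 5 with the litter block, 1 higher and 4 lower.

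**Figure D3:**
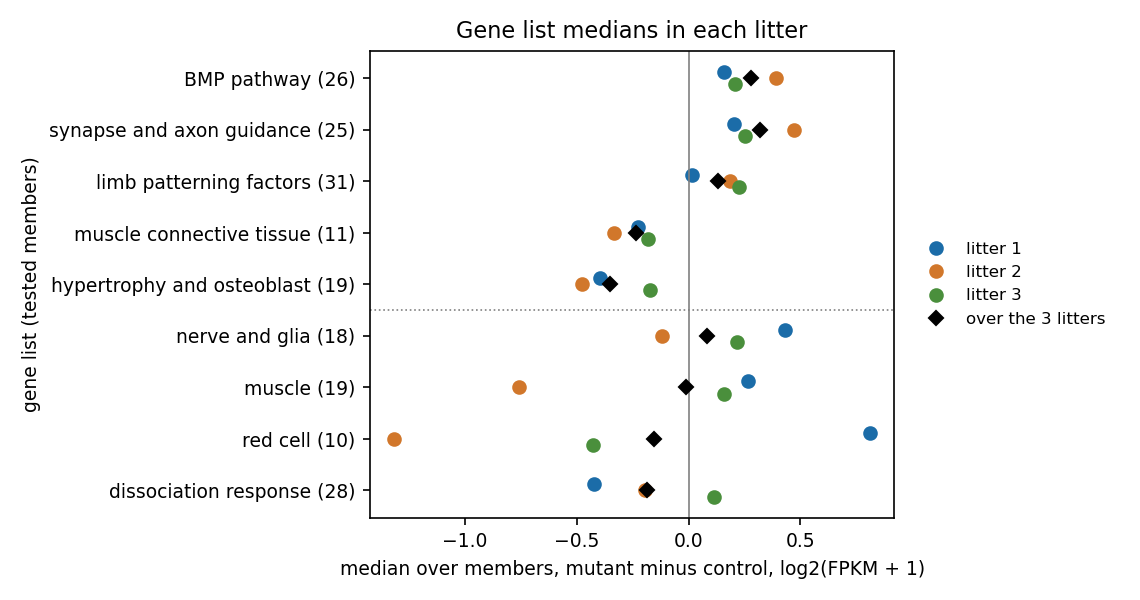
Median over list members of the mutant minus control difference on the log2(FPKM + 1) scale (horizontal axis), with coloured points for litters, black diamonds over the 3 litters, and tested members in brackets. The 5 lists above the dotted line passed camera at the preset correlation, and the red cell list below it runs from -1.32 in litter 2 to 0.81 in litter 1.

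With all tested members, other skeletal and signalling lists did not pass camera. The joint list had a median of 0.04 (adjusted p = 0.0688), with Gdf5 and Enpp2 past the threshold adjusted over the list alone, and Enpp2, the autotaxin gene, at 16.1 ± 1.44 and 35.2 ± 6.11 FPKM. Its 12 members outside the deposited list had a median of 0.04 and passed upward (camera adjusted p = 0.0433, and adjusted p = 0.509 with an estimated correlation), a test run after the data were seen. In that test the BMP, synapse, hypertrophy and muscle connective tissue lists stayed past the threshold (camera adjusted p = 3.68e-05, 0.000290, 8.44e-05 and 0.0113, and adjusted p = 0.423, 0.509, 0.509 and 0.423 with an estimated correlation). The tendon list had a median of -0.19 (adjusted p = 0.440). Its member Kera, the corneal and tendon proteoglycan keratocan, passed over the list alone, at 45.4 ± 4.98 FPKM in the controls and 96.2 ± 15.5 FPKM in the mutants. Posterior Hox genes had a median of 0.14 (adjusted p = 0.165), with Hoxd11 at 18.5 ± 1.72 and 25.4 ± 2.51 FPKM. With the litter block, 6 Hox genes passed in limma over the list alone, Hoxd11, Hoxd10 and Hoxa11 higher and Hoxc9, Hoxc10 and Hoxc11 lower (adjusted p = 0.0225, 0.0138 and 0.0232 for these 3, against 0.188, 0.223 and 0.188 without it). Hoxc9, Hoxc10 and Hoxc11 had log2 changes of -0.66, -0.70 and -0.72, lower in 3 of 3 litters. The chondrocyte list had a median of 0.07 and a mean of -0.07 (adjusted p = 0.603), with Sox5, a partner of Sox9 in cartilage, at 6.13 ± 0.852 and 11.0 ± 1.45 FPKM. Hedgehog, Wnt and FGF lists had medians of -0.04, 0.05 and -0.06 (adjusted p = 0.894, 0.434 and 0.846), with the Wnt mean at -0.02 against an upward test. Ptch1, the hedgehog receptor, was at 23.1 ± 1.72 FPKM in the controls and 15.4 ± 2.46 FPKM in the mutants, and Etv4, a target of FGF signalling, at 18.6 ± 2.13 and 10.4 ± 2.84 FPKM. The proliferation list had a median of -0.08 (adjusted p = 0.393). Adjusted over each list alone with the block, 4 tendon genes passed higher and 5 lower, 1 chondrocyte gene higher and 5 lower, 2 hedgehog genes higher and 4 lower, 3 Wnt genes higher and 2 lower, 1 FGF gene higher and 4 lower, 3 joint genes higher and 0 proliferation genes.

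Markers of other cell types and of cell handling also did not pass camera. Surface ectoderm had a median of -0.13 (adjusted p = 0.361), endothelium -0.19 (adjusted p = 0.165), nerve and glia 0.08 (adjusted p = 0.286), muscle -0.01 (adjusted p = 0.846) and red cells -0.16 (adjusted p = 0.891). The muscle and red cell tests pointed upward although their medians and means were below 0. Medians in litters 1, 2 and 3 were 0.81, -1.32 and -0.43 for red cells and 0.27, -0.76 and 0.16 for muscle. They were 0.28, -0.60 and 0.03 for surface ectoderm, -0.17, -0.51 and 0.01 for endothelium, and 0.43, -0.12 and 0.22 for nerve and glia. Each of these lists was thus below 0 in litter 2, where the share of other cells may have differed along with genotype, which was not tested. The dissociation response had a median of -0.19 and a mean of 0.01 (adjusted p = 0.434). Of its heat-shock members, Hspa1a and Hspa1b had log2 changes of 3.49 and 3.24 in litter 1, 3.49 and 3.11 in litter 2, and 0.31 and 0.49 in litter 3. The others, Hspa8, Dnajb1, Hsp90aa1 and Hsph1, ran from -0.64 to 0.49 in litters 1 and 2 and from -1.21 to 0.19 in litter 3. Adjusted over each list alone with the block, 4 dissociation genes passed higher and 2 lower, 2 surface ectoderm genes and 1 endothelial gene lower, 1 red cell gene higher, and 0 genes of muscle, nerve and glia or sex linkage, where 0 passed in each of these lists without it. Too few leukocyte markers were tested for a list test. Coro1a, an actin-binding protein of leukocytes, was at 6.81 ± 1.33 FPKM in the controls and 6.92 ± 0.968 FPKM in the mutants. The leukocyte marker Cd68 was at 2.86 ± 1.64 and 2.53 ± 0.613 FPKM. Laptm5, another, was at 2.69 ± 1.12 and 2.10 ± 1.44 FPKM, lower in 3 of 3 litters. Sex-linked genes had a median of -1.03 (adjusted p = 0.361). The Y-linked genes Eif2s3y and Kdm5d were listed at 0 in the litter 2 mutant column, where the X inactivation transcript Xist was at 178 FPKM, against 12.1 to 73.0 FPKM in the other columns. In the litter 2 control Eif2s3y was at 23.9 FPKM and Kdm5d at 4.78 FPKM. Sex composition thus differed along with genotype in litter 2, and their effects cannot be told apart there. In litter 1 Xist was at 12.1 FPKM in the control and 36.8 FPKM in the mutant. Eif2s3y was there at 21.6 and 22.4 FPKM and Kdm5d at 8.86 and 6.55 FPKM, so a difference in sex composition is not excluded in litter 1.

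The deposited list of genes called directly repressed by Shox2 was higher in the mutants as a group. Its 978 tested members had a median log2 change of 0.08, against -0.05 in the 11336 other rows (camera p = 6.61e-12, and p = 0.000289 with an estimated correlation). The list may have been chosen on these samples, so its direction is not independent evidence. Members were higher in 3 of 3 litters for 36.5%, against 13.9% of other rows, and higher without overlap for 138, or 14.1% against 3.37%. At an unadjusted p under 0.05, 97 members were higher and 8 lower, and with the litter block 179 higher and 22 lower. Adjusted over the list alone in limma, 1 member passed, or 52 with the block, 49 higher and 3 lower, which is again not independent evidence. The largest changes were those of Shox2, which the list itself holds, Gria2, Cbln2, Bhlhe40 and Glis3. Bhlhe40, a repressor of the clock and hypoxia responses, was at 2.05 ± 0.719 FPKM in the controls and 9.68 ± 7.50 FPKM in the mutants. Glis3, a zinc-finger transcription factor, was at 2.12 ± 0.668 and 6.49 ± 0.718 FPKM. The list took in 15 of 31 limb patterning factors and 7 of 21 Wnt genes, against 7.94% of all tested rows (Fisher's exact test, adjusted p = 5.08e-08 and 0.00841). It took in 6 of 25 genes of synapses and axon guidance (Fisher's exact test, adjusted p = 0.0786). 

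**Figure D4:**
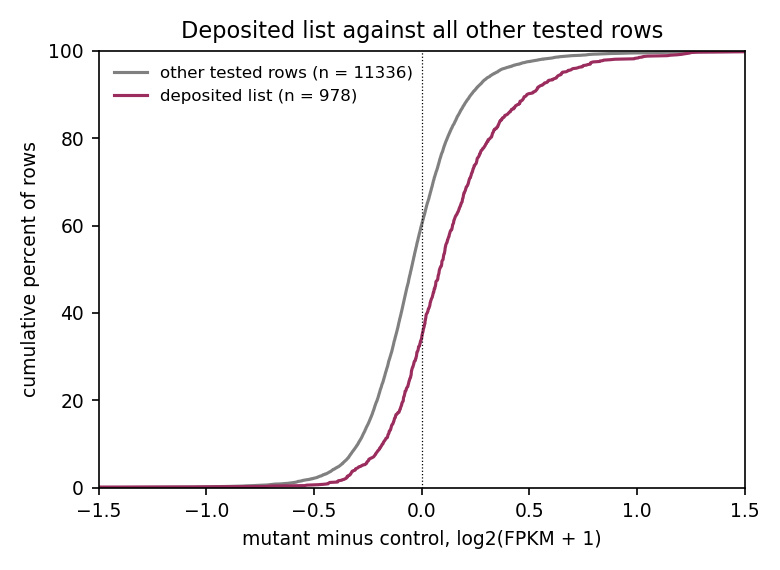
Cumulative percent of rows (vertical axis) by mutant minus control difference on the log2(FPKM + 1) scale (horizontal axis), for 978 members of the deposited list and 11336 other tested rows. The curve of the list lies to the right of the other, with medians of 0.08 and -0.05.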

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

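The fits that leave out a litter pair, those that join the block with another setting, and the one without small RNA rows were chosen after the data were seen. The count of called genes was 0 except for 15 with column weights, 303 and 27 with the block without the litter 2 and litter 3 pairs, and 0 to 1 without single replicates. Such 2-pair fits leave 1 residual degree of freedom per gene. The count at an unadjusted p under 0.05, 439, was 752 without a filter, 238 with a mean of 5 FPKM or more, 1088 with column weights, 1433 with the litter block, and 229 to 563 without single replicates. It was 201 without the litter 3 pair, 712, 1616 and 1233 with the block without the litter 1, 2 and 3 pairs, 1388 with the block and a pseudocount of 0.1, and 1418 with the block and no trend. The count of called lists, 5, was 8 without a filter, 3 with a mean of 5 FPKM or more, 10 with column weights, 0 with an estimated correlation, 3 to 10 without single replicates, and 8 and 3 with the block without the litter 2 and litter 3 pairs. The block ended the call of the muscle connective tissue list and changed no other call. Shox2 ran from -3.56 to -2.32 without single replicates, and was -2.37 and -3.58 with the block without the litter 2 and litter 3 pairs. The dissociation response was called upward with column weights (median 0.0897), and the red cell list, whose median ran from -0.76 to 0.32 without single replicates, downward without mutant replicate 1 and with the block without the litter 1 pair (-0.49). The cause was not tested, apart from the smaller number of samples or rows. Of the named genes, 69 values passed the threshold under an alternative and 1521 stayed on their side of it. Another 11 changed sign without passing it: Coro1a and Snora16a with column weights (-0.0180 and -0.53), Coro1a, Tubb3 and Nefm without single replicates (-0.12 to 0.11, -0.56 to 0.44 and -0.0360 to 1.01), Tubb3 without the litter 3 pair (-0.0800) and with the block without the litter 1 and 3 pairs (-0.46 and -0.0800), and Coro1a with the block without the litter 2 pair (-0.22). The deposited list ran from 0.06 to 0.12 and stayed past the threshold. Fits with whole limbs and with the litter 1 mutants as 2 replicates or averaged were not run, since the columns used here do not hold them. Depth is unknown.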

Other observations

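The tests of explanations in this part, the low-oxygen list and the counts over splits were chosen after the results they bear on were seen, while the fits with and without the litter block were chosen beforehand. Genes of the response to low oxygen and of glucose use were higher in the mutant columns, a theme noticed in the values and then drawn up as a list of 43 tested genes. Of these, 39 were higher in 3 of 3 litters and 0 were lower in 3 of 3, with a median log2 difference of 0.74. Slc2a1, the glucose transporter GLUT1, was at 35.1 ± 6.27 FPKM in the controls and 107 ± 58.4 FPKM in the mutants. Bnip3, a mitophagy receptor, was at 15.4 ± 5.01 and 54.4 ± 28.6 FPKM, and Slc16a3, a lactate exporter, at 24.6 ± 1.28 and 61.6 ± 18.6 FPKM. The glycolytic enzyme gene Hk2 was at 13.4 ± 2.17 and 29.7 ± 10.1 FPKM, and Pdk1, a kinase that restrains pyruvate dehydrogenase, at 19.6 ± 1.93 and 35.4 ± 2.72 FPKM. With all 6 columns, no gene of the list passed limma's adjusted threshold, with or without the litter block. The deposited list held 2 of the 43, against 7.94% of all tested rows, a difference not tested. Mmp9, a matrix protease of osteoclasts and other cells, was at 4.78 ± 2.48 and 1.23 ± 0.618 FPKM.

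For this low-oxygen theme, the 28 members not looked at first had a median of 0.57. Their camera p was 0.0410 with an estimated correlation, or 0.0438 with the block. For the whole list these p were 0.0224 and, with the block, 0.0580, so the support is weak. The theme was chosen on these same columns, and its genes may move together. The 28 members therefore bear on the picking of members only, and selection of the theme by its values stays open. In litter 3 the list's median was 0.77 times its mean over litters 1 and 2 (95% interval over genes 0.62 to 1.06), while Hspa1a and Hspa1b shrank to 0.12 times. In that litter Hspa1a was at 0.275 FPKM in the control and 0.583 FPKM in the mutant, and Hspa1b at 0.493 and 1.09 FPKM. The log2(FPKM + 1) scale compresses changes at such low values, and the interval does not cover the spread between litters. What raised Hspa1a and Hspa1b was not tested. Whether the same source, such as handling, raised the low-oxygen list therefore cannot be decided here. A different delay or low oxygen before lysis may still differ between genotypes, and a genotype effect was not tested apart from it, so both stay open.

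Shox2 stayed at 46.2% of its control in the litter 3 mutant column. Exchanged labels within litter 3 are argued against, because 90.7% of 43 genes that differed alike in litters 1 and 2 went the same way in litter 3 (95% exact interval over genes 77.9% to 97.4%). That interval takes the genes as independent, though all rest on the same litter 3 columns and may move together. Cells with a working allele may have been mixed in, and Shox2 alone would put their share at 41.6%, so that other effects would shrink to 0.58. Effects in litter 3 were 0.61 of those in litter 2 for 93 genes selected in litter 1 (95% interval over genes 0.46 to 0.84), but 1.13 of those in litter 1 for 612 genes selected in litter 2 (0.77 to 1.77), and 9 choices of selection limits gave 0.57 to 1.31 and 1.03 to 1.26. For 73 genes selected in litter 3, effects in litter 1 were 0.66 of those in litter 2 (0.35 to 1.23), so a ratio under 1 may rest on large effects in litter 2, and mixing and a biological difference between litters cannot be told apart here.

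Higher genes of synapses and axon guidance may come from more nerve or glial RNA. A sort on GFP is meant to remove cells outside the Shox2 lineage, but RNA of such cells may remain. Hbb-y, a globin gene of the red cell list, was at 182 to 567 FPKM across the control and mutant columns. The abundant axonal gene Gap43 was at 27.5, 39.1 and 32.5 FPKM in the controls and 39.3, 35.5 and 42.7 FPKM in the mutants of litters 1, 2 and 3. In litter 2 more nerve or glial RNA as the source is argued against. There Tubb3 and Nefm had log2 changes of -1.11 and -0.84. The median of the guidance list exceeded that of nerve and glial markers by 0.59 (95% interval over genes 0.31 to 1.43). In litters 1 and 3 the difference was -0.23 (-0.75 to 0.12) and 0.0353 (-0.17 to 0.38), so nerve RNA and a change in the sorted cells cannot be told apart there. A biological effect of the genotype was not tested separately.

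The 6 columns make 10 splits into 3 and 3, too few for a share under 0.05. For called genes the real split gave 0, so that all 10 splits gave as many by construction and this count decides nothing, and the highest other gave 8. At an unadjusted p under 0.05 the real split gave 439, 5 splits gave as many, and the highest other gave 1849, a split that kept the litter 1 columns together and so points to litter structure. For called lists the real split gave 5, 5 splits gave as many, and the highest other gave 9. With the litter block, among the 4 splits that part each litter, the real one gave 1433 genes at an unadjusted p under 0.05, as many in 1 split, and the highest other gave 231, but the called lists were 4 in the real split and up to 9 in the others.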
